A study of Mus musculus with 3 samples.

How the data were processed

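RNA from the cytosolic fraction of mouse bone marrow-derived macrophages was measured by ribosomal RNA-depleted total RNA sequencing in 3 libraries, per the labels. Bone marrow-derived macrophages are primary cells grown from marrow progenitors. The cells came from the C57BL/6J strain and had been exposed to 100 ng/ml Lipid A for 40 minutes. Lipid A is the part of bacterial lipopolysaccharide that is recognised by Toll-like receptor 4. Each library started from 1 µg of RNA, with a size range of 250 to 400, per the labels. The labels number the libraries as biological replicates 1, 2 and 3 with separate sample records that share 1 donor record, so it is not known from them whether the cells came from separate animals. The p-values of the gene pairs and of the spread test therefore measure the spread between these 3 libraries, which may be partly technical. Those of the list comparisons refer to the choice of genes. All 3 libraries form 1 group. Libraries from unstimulated cells and from other fractions were not analysed here, so no value below is a change caused by Lipid A or by fractionation.

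Each library had a gene table and 2 transcript tables on mouse build mm10 with annotation GENCODE M21, per the deposited notes of each library. The gene table and the first transcript table held expected counts and TPM that the authors derived from a transcriptome alignment, per the deposited notes. The second transcript table held estimated counts and TPM that the authors derived from the reads directly, per the deposited notes. TPM is a transcript abundance that the authors scaled to effective length and to the same sum over all features of each deposited table. The names and versions of the quantification tools are not given in the sources used here. Whether strand was used in counting is not given either, so genes that overlap, antisense pairs and near-identical copies are uncertain where their reads could be divided in more than 1 way. All 55536 gene IDs and 141862 transcript IDs matched GENCODE M21, which gave the symbols, coordinates and RNA classes. The second transcript table lacked 95 of these transcripts. The gene table also listed 97 spike-in features and 26248 features with numeric IDs; the latter had a count of 0, and both were kept out of library sizes and tests.

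The deposited expected counts summed to 37861150, 37136495 and 58889061 over genes in replicates 1, 2 and 3. A count of 0 allowed up to 0.0792, 0.0808 and 0.0509 CPM, which is counts scaled to a fixed library sum, in these libraries, with 3 counts taken as the limit. Such limits and the 95% Wilson intervals given for shares cover counting error only. Replicate pairs differed by more than sampling noise, with chi-square per degree of freedom between 58.5 and 145 over genes with at least 20 reads in the pair, as separately prepared libraries commonly do. Each library was counted as a replicate because the labels number it as one. Pearson correlations of log2(TPM + 1) over protein-coding genes were 0.993 to 0.996. These are correlations across genes, and genes are not independent replicates.

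The tests, 20 gene lists (223 entries, 222 different genes), 22 gene pairs, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. All 223 list entries matched a gene. Levels are TPM of the gene table, given as mean ± SD over the 3 libraries. Lists were compared on the mean over libraries of log2(TPM + 1), by a two-sided permutation of list labels over genes with 100000 resamples, or by exact enumeration where a list had under 10 genes. The 4 main list comparisons form 1 family and the 10 comparisons of single lists another for Benjamini-Hochberg adjustment. Pair ratios were differences of log2(TPM + 1) within a library, tested with limma together with 5000 random pairs of detected protein-coding genes that informed the prior variance. A difference on the log2(TPM + 1) scale understates that of genes with low values.

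Spread between replicates was tested in edgeR on expected counts rounded to whole numbers. The steps were filterByExpr, TMM normalization, an intercept-only fit with trended dispersion and a goodness-of-fit chi-square test with Benjamini-Hochberg adjustment at 0.05. Median spread and retained-intron share of a list were placed among 10000 random lists of protein-coding genes of the same size, matched on mean expression in 20 bins. A list was taken to stand apart above percentile 97.5 or below percentile 2.5. These percentiles describe the 3 libraries and are not tests of a population. The main transcript of a gene was that with the highest mean TPM. The retained-intron share was the share of a gene's TPM in transcripts annotated as retained introns.

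The genes named by rule were the 3 with the highest mean TPM of each list, or the 5 highest and any below 0.1 TPM for the immediate early, early cytokine, negative feedback, late response and interferon-stimulated lists. The rule also took the genes of the pairs, the 10 highest protein-coding genes of the nuclear genome, the 10 genes with the smallest adjusted p in the test of spread, and response genes whose main transcript differed between the transcript tables. Genes named outside that rule were chosen after their values were seen.

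Alternatives were a pseudocount of 0.1, leaving out genes with mean TPM under 1, CPM without length normalization, the second transcript table and leaving out each replicate in turn. A further alternative multiplied every TPM by 1 factor per library so that 32169 protein-coding genes and lncRNAs of the nuclear genome had the same sum in each library. The spread was also tested with DESeq2 size factors, the DESeq2 dispersion trend, other count filters and protein-coding genes alone.

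A check of sequencing depth as a cause of the replicate patterns was dropped before it was run, since the ratios were already scaled to depth. That reason does not cover the retained-intron shares, for which an effect of depth was not tested. The list permutation, the gene pairs, the spread test and the matched lists for spread were tested on simulated data, and the other steps were not. For the early against late comparison, 7% of 200 random lists drawn from 11451 genes had p under 0.05, and 99% of 200 lists shifted by 3 on the log2 scale did. For the gene pairs, 5% of 400 simulated pairs with no difference had an unadjusted p under 0.05, and 93.5% did at a log2 ratio of 1. For the spread test over 12063 genes, 29% of 100 genes raised or lowered 2-fold in 1 library and 93% of 100 altered 4-fold were recovered, with 1 false call. For the spread of the early lists among matched lists over 11164 genes, 4% of 100 random lists lay above percentile 97.5. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.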

Results

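Cytosolic RNA of mouse bone marrow-derived macrophages was sequenced in 3 libraries after 40 minutes of exposure to 100 ng/ml Lipid A, the ligand portion of bacterial lipopolysaccharide. The libraries are biological replicates 1, 2 and 3 of 1 group, with 37861150, 37136495 and 58889061 expected counts in genes. With no second group, the comparisons are between sets of genes within the same libraries, between the members of fixed gene pairs, between the replicates, and between 2 quantifications of the transcripts. Levels are TPM as mean ± SD over n = 3 libraries, and coordinates are those of mouse build mm10 with annotation GENCODE M21.

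Small cytoplasmic and nuclear RNAs of the signal recognition particle and of RNA processing made up most of the TPM. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, held 54.5% ± 4.55 of TPM (SD, n = 3), although they took 7.25% ± 2.00 of the expected counts. Reads of these near-identical copies cannot be assigned with certainty to either gene. TPM divides by effective length, so the TPM share of such short RNAs depends on the length assigned to them. In replicate 1 Rn7s2 had 1.34e+06 expected counts and 281106 TPM, whereas the longer Psap had 723157 counts and 5532 TPM. The effective length was not checked, so the TPM shares of 7SL and other small RNAs are uncertain as shares of RNA molecules. Protein-coding genes of the nuclear genome held 88.9% ± 3.18 of the counts and 30.8% ± 6.54 of TPM. Their share of TPM was 32.8%, 36.2% and 23.5% in replicates 1, 2 and 3, which lowers the TPM of coding genes as a whole in replicate 3. 7SK RNA, a nuclear regulator of transcription elongation, took 0.772% (95% Wilson interval 0.769 to 0.775), 0.631% (0.628 to 0.634) and 1.70% (1.69 to 1.70) of the counts in replicates 1, 2 and 3. Genes of the mitochondrial genome took 0.557% ± 0.131 of the counts, and annotated rRNA genes 0.0452% ± 0.0371.

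**Figure D1:**
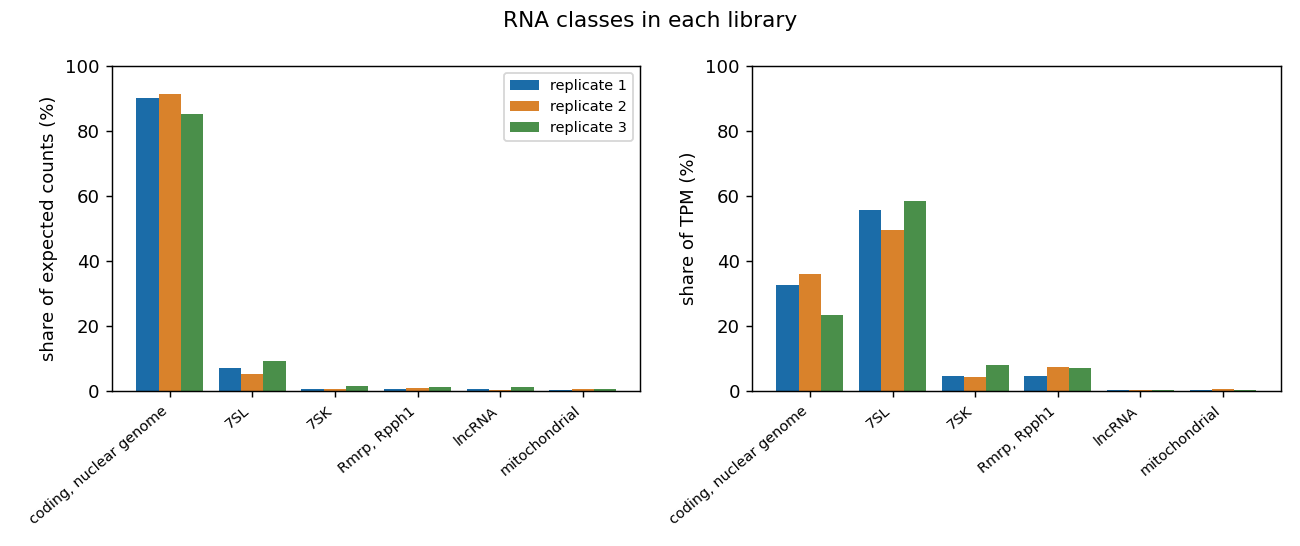
Share of expected counts (left, percent) and of TPM (right, percent) taken by 6 RNA classes in each of the 3 libraries; each bar is 1 library. Coding genes took 85.3% to 91.3% of the counts but 23.5% to 36.2% of TPM, while 7SL RNA took 49.5% to 58.4% of TPM. The TPM share of short RNAs depends on an effective length that was not checked.

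The 10 most abundant messages of protein-coding genes of the nuclear genome had means from 2473 to 10506 TPM. Ftl1 and Fth1, the light and heavy chains of ferritin, stood at 10506 ± 2210 and 10025 ± 3268 TPM. Lyz2, the lysozyme of myeloid cells (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321), stood at 5974 ± 1620 TPM. Psap, the precursor of the saposins, stood at 4925 ± 688 TPM, the cathepsins Ctsd and Ctsb at 4208 ± 593 and 3066 ± 904 TPM, and the selenium carrier Selenop at 3244 ± 948 TPM. Gpnmb, Tmsb4x and Actb followed at 2518 ± 329, 2505 ± 386 and 2473 ± 624 TPM. A protein-coding gene counted as detected at a mean of at least 0.1 TPM, which 11458 genes reached, and the highest 10% of these began at 42.1 TPM.

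The first question was how far genes known to respond to Toll-like receptor 4 within minutes stood above those known to follow later. Immediate early genes, which need no new protein to be transcribed, were all above 1 TPM, and 14 of 18 were in the highest 10%. Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) stood at 519 ± 151 TPM, Junb at 502 ± 121, Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) at 433 ± 58.4, Klf6 at 284 ± 84.9 and Ier2 at 269 ± 40.1. Of the 12 early cytokine genes, 10 were in the highest 10%. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) was the highest at 1065 ± 418 TPM, followed by the neutrophil attractant Cxcl2 at 649 ± 220, the chemokines Ccl3 and Ccl4 at 523 ± 237 and 482 ± 163, and Il1b at 485 ± 187. Cxcl3 was the lowest of this list, at 0.387 ± 0.0764 TPM. Of the 16 negative feedback genes, 8 were in the highest 10%. They included Zfp36, which promotes decay of AU-rich messages, at 927 ± 295 TPM, and Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647), the inhibitor of NF-κB, at 819 ± 213. The phosphatase gene Dusp1 stood at 495 ± 127, the ubiquitin-editing enzyme Tnfaip3 at 302 ± 84.7 and the nuclear IκB protein Nfkbiz at 294 ± 116.

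The late response list, of genes that commonly need new protein or chromatin remodelling, was far lower, with 2 of 18 genes in the highest 10% and 8 of 18 below 1 TPM. The anti-inflammatory cytokine Il10 was its highest gene at 104 ± 47.5 TPM, then Ccl5 at 45.4 ± 28.9, Saa3 at 28.6 ± 20.1, Ebi3 at 27.8 ± 8.36 and Acod1, which makes itaconate, at 18.8 ± 9.23. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) stood at 0.783 ± 0.595 TPM, or 0.455 without replicate 1, and Il12b at 2.13 ± 1.45. Csf3, Nos2 and Il12a had means of 0.0667, 0.0233 and 0.00667 TPM and 8, 11 and 1 expected counts in replicate 3. Il12a had a count of 0 in replicates 1 and 2, which allowed up to 0.0671 TPM in the less sensitive library. The median of the early lists together exceeded that of the late list by 6.27 on the log2(TPM + 1) scale (two-sided permutation test over 46 and 18 genes, p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 2e-05 over 4 comparisons). The difference was 6.41, 6.31 and 6.26 in replicates 1, 2 and 3. The genes of a list are not independent replicates, and the p of each list comparison refers to the choice of genes, not to new animals. Taken singly against the late list, the immediate early, early cytokine and negative feedback lists differed by 6.27, 6.61 and 4.16 (permutation tests, adjusted p = 0.0001, 0.000511 and 0.000511 over 10 comparisons). With genes under 1 TPM left out the difference was 3.42 (permutation p = 0.0006), and over all alternatives it lay between 3.42 and 7.05.

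Interferon-stimulated genes lay between these groups. All 19 had a mean of at least 1 TPM, and 6 were in the highest 10%. Ifit2 stood at 98.0 ± 40.4 TPM, the chemokine Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889) at 91.5 ± 58.7, the antiviral Rsad2 at 84.3 ± 23.1 and Ifit3 at 78.3 ± 25.6. The early lists exceeded them by 2.92 on the log2 scale (permutation test, 46 and 19 genes, p = 0.00011; adjusted p = 0.000147), by 2.71, 2.80 and 3.22 in replicates 1, 2 and 3, and by 2.06 to 3.04 over the alternatives. The interferon-stimulated list exceeded the late list by 3.35 (permutation test, adjusted p = 0.000354). Without unstimulated cells, these levels do not separate RNA made in response to Lipid A from RNA present before it.

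Genes of the receptor pathway itself were expressed at moderate levels. All 20 Toll-like receptor 4 pathway genes had at least 1 TPM, with 1 in the highest 10% and a median of 13.1 TPM. The co-receptor Cd14 stood at 370 ± 76.9 TPM, the kinase adaptor Tab2 at 32.4 ± 9.72 and Tlr4 itself at 30.1 ± 6.42. The 5 NF-κB subunit genes were within a narrow range, from Rela at 34.7 ± 12.8 TPM, Rel at 26.3 ± 9.35 and Nfkb1 at 21.9 ± 3.29 to Nfkb2 at 16.7 ± 2.89 and Relb at 11.6 ± 2.46.

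**Figure D2:**
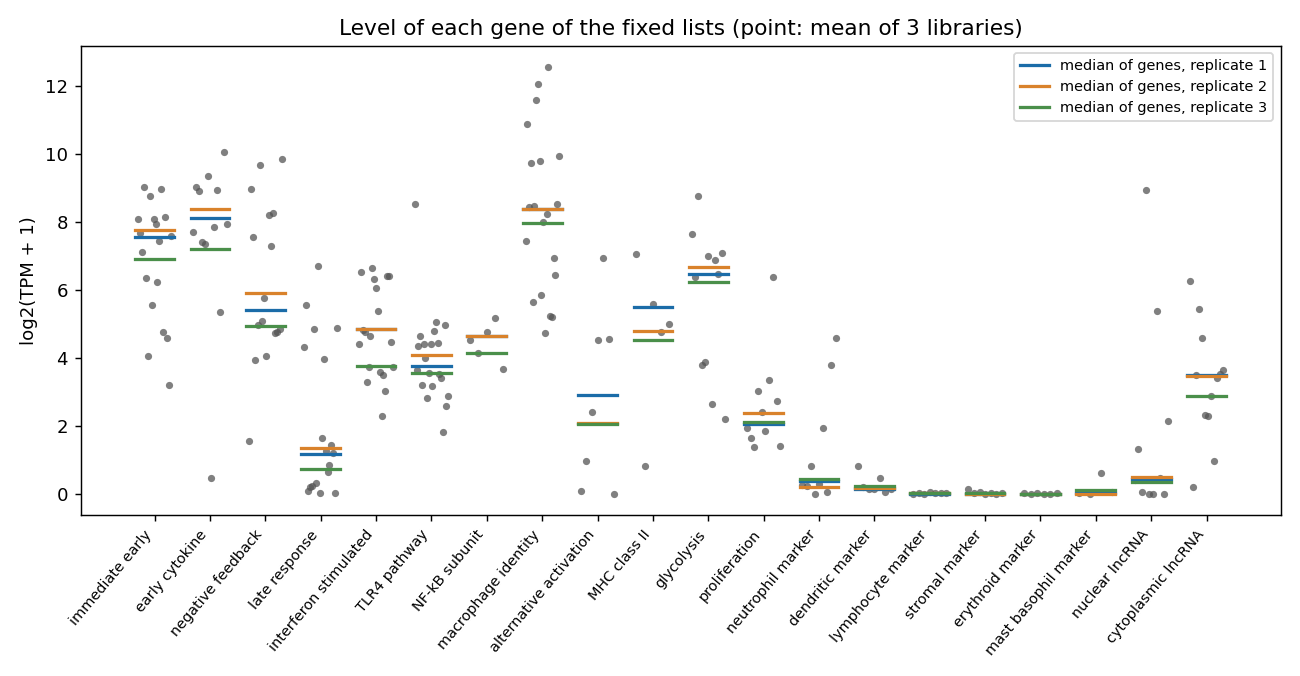
Level of each gene of the 20 lists on the log2(TPM + 1) axis; a point is the mean of 3 libraries for 1 gene, and the coloured bars are the median over the list's genes in replicates 1, 2 and 3. The medians of the immediate early, early cytokine and negative feedback lists lie above that of the late response list in each library, and the lymphocyte, stromal and erythroid points lie near 0.

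Markers of cell type were those of macrophages. All 20 macrophage genes had at least 1 TPM and 17 were in the highest 10%, led by Lyz2, Ctsd and Ctsb. The median of this list exceeded that of 40 markers of neutrophils, dendritic cells, lymphocytes, stromal cells, erythroid cells and mast cells or basophils by 8.27 on the log2 scale (permutation test, p = 1e-05, the smallest possible; adjusted p = 2e-05), by 8.38, 8.34 and 7.92 in replicates 1, 2 and 3, and by 4.56 to 11.32 over the alternatives. Against each of the 6 lists alone the difference was between 8.02 for neutrophils and 8.30 for erythroid cells (exact permutation tests, adjusted p from 0.000354 to 0.000941). Neutrophil markers were the highest of the others. S100a9 and S100a8, the subunits of calprotectin, stood at 22.9 ± 2.84 and 12.7 ± 3.71 TPM and the granule protein Ngp at 2.80 ± 0.537, whereas Ly6g had a count of 0 in each library, which allowed up to 0.142 TPM. Among dendritic cell markers Ccr7 reached 0.75 ± 0.131 TPM, Siglech 0.377 ± 0.0115 and Cd209a 0.143 ± 0.0777. The highest lymphocyte genes were Cd79a, Ms4a1 and Klrb1c at 0.0267, 0.0233 and 0.0133 TPM, the highest stromal genes Acta2, Col1a2 and Col1a1 at 0.0900, 0.0400 and 0.0233, and the highest erythroid genes Alas2, Hba-a1 and Klf1 at 0.0100, 0.00667 and 0.00667. In the mast cell and basophil list Kit stood at 0.510 ± 0.200 TPM, and Mcpt8 and Cpa3 at 0.0433 and 0.0200.

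Other macrophage programmes were represented unevenly. In the alternative activation list, the mannose receptor Mrc1 stood at 121 ± 18.4 TPM, Pparg at 22.2 ± 3.95 and Il4ra at 22.1 ± 6.38, while Arg1 stood at 0.0467 TPM with at most 2 expected counts in a library. The class II antigen presentation genes Cd74, H2-Aa and H2-Eb1 stood at 133 ± 44.7, 47.3 ± 16.3 and 30.8 ± 11.7 TPM. All 11 glycolysis genes had at least 1 TPM, and Gapdh, Aldoa and Pkm stood at 430 ± 200, 199 ± 41.5 and 133 ± 19.1. Of the 10 proliferation genes the replication clamp Pcna was highest at 82.1 ± 13.2 TPM, with Mki67 at 9.07 ± 3.24 and Cdk1 at 7.12, between 5.89 and 8.79 in the libraries.

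Because the libraries came from a cytosolic fraction, lncRNAs known to stay in the nucleus were compared with lncRNAs known from the cytoplasm. Malat1, a nuclear speckle RNA (ENSMUSG00000092341.3, chromosome 19), was nevertheless among the abundant transcripts, at 484 ± 358 TPM, with 291, 264 and 898 TPM in replicates 1, 2 and 3. Without replicate 3 its mean was 278 TPM. The paraspeckle RNA Neat1 stood at 40.8 ± 32.5 TPM, or 22.3 without replicate 3, and the X-inactivation RNA Xist at 3.42 ± 2.00. In the cytoplasmic list, 2900097C17Rik stood at 75.8 ± 14.2 TPM, the snoRNA host Gas5 at 41.8 ± 15.8 and 1700020I14Rik, matched as a synonym of Oip5os1, at 22.8 ± 4.68. The median of 10 nuclear lncRNAs was lower than that of 12 cytoplasmic lncRNAs, with a difference of -2.99 on the log2(TPM + 1) scale (permutation test, p = 0.0141; adjusted p = 0.0141), and of -3.07, -2.97 and -2.53 in replicates 1, 2 and 3. This call rested on nuclear lncRNAs that were nearly absent, 4 of which were under 0.1 TPM. With genes under 1 TPM left out, 4 nuclear and 10 cytoplasmic lncRNAs differed by 0.11 in the other direction (exact permutation p = 0.830), and without length normalization the difference was -0.45 (permutation p = 0.532).

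Ratios within 22 fixed gene pairs were compared next, to order related genes within the same libraries. In 20 pairs the log2 ratio differed from 0 at adjusted p under 0.05 (limma, Benjamini-Hochberg over 22 pairs). Tnf exceeded Il6 by 9.19 ± 0.51 on the log2(TPM + 1) scale (SD, n = 3; limma adjusted p = 1.28e-11) and Il1b by 1.13 ± 0.07 (adjusted p = 1.16e-05), each in 3 of 3 libraries. Cxcl2 exceeded Cxcl1 by 2.01 ± 0.09 and Cxcl10 by 3.07 ± 0.80. Nfkbia exceeded the other IκB genes Nfkbib and Nfkbie by 4.63 ± 0.26 and 5.61 ± 0.20. Among immediate early partners, Fos exceeded Fosb by 3.31 ± 0.56, Egr1 exceeded Egr2 by 2.66 ± 0.13 and Junb exceeded Jun by 1.53 ± 0.11. Il1b exceeded Il1a by 1.08 ± 0.31 and Dusp1 exceeded Dusp2 by 1.40 ± 0.28. Ccl4 exceeded Ccl5 by 3.54 ± 1.36, with 5.11, 2.66 and 2.86 in replicates 1, 2 and 3. The adaptor Myd88 exceeded Ticam1 by 1.24 ± 0.24, Irak4 exceeded its inhibitory relative Irak3 by 0.72 ± 0.04, and Rela exceeded Relb by 1.46 ± 0.40. Il12b exceeded Il12a by 2.10, 1.84 and 0.56 in replicates 1, 2 and 3, and Malat1 exceeded Neat1 by 3.58 ± 0.28. Ifit1 was lower than Ifit2, with a log2 ratio of -2.01 ± 0.20 (limma adjusted p = 2.12e-07). The size of many ratios rested on the length normalization of TPM, without which 10 of the 22 moved by over 1.5-fold. Without it Junb exceeded Jun by 0.63, Fos exceeded Fosb by 2.42, Il1b exceeded Il1a by 0.43 and Myd88 exceeded Ticam1 by 0.64. Ratios with a gene near 0 also moved with other settings. Tnf exceeded Il6 by 10.38 with a pseudocount of 0.1, by 10.01 with rescaled TPM and by 8.22 in the second transcript table, and Il12b exceeded Il12a by 4.05 and 2.66 in the first 2 of these. Ccl4 exceeded Ccl5 by 2.76 without replicate 1.

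The closest called pairs were those of NF-κB subunits. Rela exceeded Rel by 0.39 ± 0.12 and Nfkb1 exceeded Nfkb2 by 0.38 ± 0.06 (limma, adjusted p = 0.0191 for both). The Rela call was lost whichever replicate was left out (limma adjusted p from 0.0520 to 0.0745), though the ratio was still 0.35 to 0.46, and it was -1.29 without length normalization. The Nfkb1 call was lost without replicate 1, without replicate 3 and in the second transcript table (limma adjusted p = 0.0782, 0.0660 and 0.251), with ratios of 0.41, 0.36 and 0.21. Ccl4 and Ccl3 did not differ beyond the spread between libraries, with a log2 ratio of -0.06 ± 0.50 (limma adjusted p = 0.789), and neither did Arg1 and Nos2, both near 0, with 0.03 ± 0.06 (limma adjusted p = 0.811).

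The spread between replicates was then set against that of genes of similar abundance. The median gene had an SD of 0.161 log2 units of TMM-normalized CPM. Of 12250 genes tested in edgeR, 209 varied more than the trend between the 3 libraries (goodness-of-fit test, Benjamini-Hochberg adjusted p under 0.05; 753 genes at unadjusted p under 0.05). Replicate 3 was the farthest library in 95 of them, higher in 71 and lower in 24, and replicate 2 in 79, higher in 21 and lower in 58. Without replicate 3 the count was 59, without replicate 1 it was 114 and without replicate 2 it was 129, and it was 116 when protein-coding genes were tested alone.

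Of the 10 genes with the smallest adjusted p, 3 were on the list of nuclear lncRNAs. Malat1 had TMM-normalized log2 CPM of 10.62, 9.89 and 12.81 in replicates 1, 2 and 3 (edgeR adjusted p = 9.85e-17), Neat1 of 8.04, 6.87 and 9.51, and Xist of 6.35, 4.94 and 7.17. The lncRNA Gm26917 had 8.50, 5.95 and 8.68, and the genes Gm14636, B430305J03Rik and Gm37033 were also lowest in replicate 2 and highest in replicate 3, with SDs of 1.25, 1.32 and 2.12, but B430305J03Rik, at 6.78 TPM, had 0 TPM in the second transcript table, so its counts are uncertain. The acute-phase gene Saa3 was lowest in replicate 1, at 1.57 against 4.05 and 4.77, and mt-Atp6 of the mitochondrial genome was lowest in replicate 3, at 5.61 against 6.93 and 8.11. The smallest adjusted p belonged to Gm49369 (ENSMUSG00000110040.1, chromosome 7, 142371096 to 142382667, minus strand), with 738, 750 and 53900 expected counts in replicates 1, 2 and 3 (edgeR adjusted p = 2.16e-93). Gm49369 overlaps Ctsd on the same strand (chromosome 7, 142375911 to 142388038), and the second transcript table gave it 25.0, 168 and 14.2 TPM, so its counts are uncertain.

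Genes of the response varied more between the libraries than other genes of their abundance, as did some lists outside the response. The 46 early response genes had a median SD of 0.25 log2 units against 0.14 in matched random lists, above each of 10000 such lists. Without replicate 3 the median SD was 0.14 against 0.12, at percentile 85.3. High spread was not particular to response genes. The class II antigen presentation, alternative activation and neutrophil lists had median SDs of 0.47, 0.31 and 0.48. These lay at percentiles 100, 99.1 and 98.9 of matched lists. Receptor pathway, NF-κB subunit, glycolysis, proliferation and dendritic cell lists did not stand apart, at percentiles from 10.1 to 91.3. The median early response gene differed by 0.22 in replicate 2 from the mean of the other 2 libraries, with 33 of 46 genes higher, and by -0.24 in replicate 3, with 36 of 46 lower. These lay above and below each of the 10000 matched lists. Immediate early genes stood apart in replicate 2, at 0.23 with 13 of 18 higher and percentile 100, but not in replicate 3, at percentile 6.24. Early cytokine genes had the larger difference in replicate 3, -0.48 with 10 of 12 genes lower, against -0.24 for negative feedback genes with 13 of 16 lower and -0.09 for immediate early genes with 13 of 18 lower. The 18 protein-coding interferon-stimulated genes were all lower in replicate 3, with a median difference of -0.44, and the 12 tested late response genes had a median of -0.34 with 8 lower, but were farther from the others in replicate 2, at 0.57 with 9 higher. Receptor pathway and NF-κB subunit genes had median differences of -0.04 and -0.02 in replicate 3. Of the 46 early response genes, 13 had an unadjusted p under 0.05 in edgeR. Of the same 46, 0 passed when adjusted over the list alone and 0 passed over all genes. With the DESeq2 dispersion trend 2 passed over all genes, Fosb and Tnfsf9, of which Tnfsf9 was chosen after its values were seen. Among the 18 immediate early genes 1, Fosb, passed when adjusted over the list alone. In the late list Acod1, Ccl5, Il12b and Saa3 passed over all genes, and 7 genes did when adjusted over the list alone, while with the DESeq2 dispersion trend Ccl5, Il10, Il12b and Saa3 passed over all genes and Acod1 did not. In the interferon-stimulated list Cxcl10, Gbp2 and Ifit1 passed over all genes with either tool, and 5 genes did in edgeR when adjusted over the list alone. Malat1, Neat1 and Xist were highest in replicate 3, in which these lists were lower.

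The spread of the macrophage list did not stand apart, though its level did in 1 library with TMM-normalized counts. Its 20 genes had a median SD of 0.17 log2 units against 0.14 in matched lists, at percentile 90.9, and the transcription factor gene Cebpb passed the edgeR test of spread, both over all genes and adjusted over the list alone. With the DESeq2 dispersion trend 2 genes passed over all genes, Cebpb and the lipid carrier Apoe, both chosen after their values were seen. On the log2(TPM + 1) scale the list lay at percentile 37.1. In replicate 2 its median differed by -0.19 from the mean of the other libraries, with 17 of 20 genes lower, at percentile 0.21 of the matched lists. That difference was -0.12 in CPM without TMM and 0.16 on the TPM scale, or -0.10 relative to the median of all protein-coding genes on that scale.

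**Figure D3:**
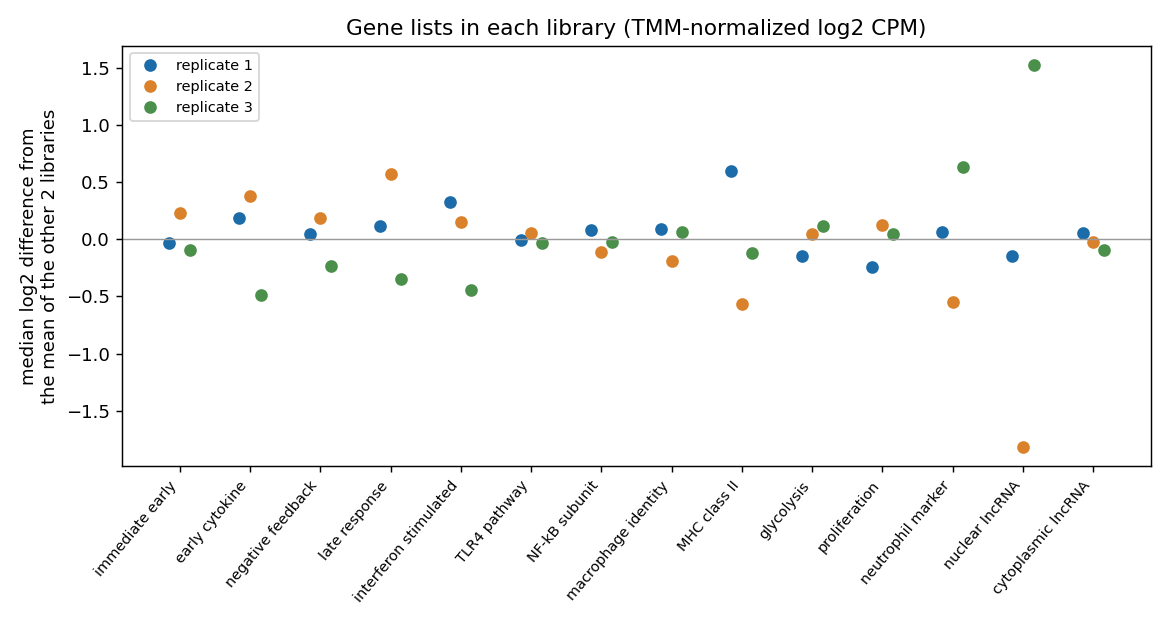
Median over the genes of 14 lists of the difference between 1 library and the mean of the other 2, in TMM-normalized log2 CPM; each point is 1 library. In replicate 3 the early cytokine list lies at -0.48 and the interferon-stimulated list at -0.44, while the 7 tested nuclear lncRNAs lie at 1.52. That last value was 0.60 on the TPM scale, or 1.00 relative to the median of all protein-coding genes on that scale.

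The 2 transcript quantifications gave the same main transcript for nearly all response genes. Of 78 genes with at least 2 annotated transcripts and 1 TPM, 75 had the same main transcript in both tables, and 76 of the 78 main transcripts in the first table were annotated as protein-coding. Tnf-201 held 100% of Tnf in the first table and 99.99% in the second, Cxcl2-201 held 95.3% ± 3.50 and 94.4% ± 3.77, and Egr1-202 held 89.5% ± 2.24 and 87.9% ± 2.80 (SD, n = 3). Other genes were divided among transcripts, such as Zfp36, whose Zfp36-201 held 57.2% ± 3.14 and 69.2% ± 6.17. The 3 genes that differed were Mx1, the kinase Map3k7 and Ifih1, a sensor of viral RNA. For Ifih1 the first table had Ifih1-201 at 61.2% ± 8.42 and the second Ifih1-202 at 45.2% ± 5.87. For Mx1 they had Mx1-205 at 43.5% ± 4.24 and Mx1-203 at 29.2% ± 3.94, both annotated for nonsense-mediated decay. For Map3k7 they had Map3k7-202 at 54.5% ± 3.93 and Map3k7-201 at 39.7% ± 3.50. Requiring the same main transcript in each library of both tables left 72 of 78 genes.

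Transcripts with a retained intron were a small part of early response RNA. Among the 16 early response genes with such a transcript, the median share was 2.41% of a gene's TPM, against 0.752% in matched random lists, at percentile 96.4. This did not pass the upper limit, whereas the second transcript table did, with 4.09% against 1.05% at percentile 98.3. Without replicate 3 the median share was 1.49% against 0.530%, at percentile 94.1. The highest shares were those of Egr3 at 30.8% ± 16.6, Nfkbie at 11.2% ± 7.68 and Tnfaip3 at 4.55% ± 3.48, where Egr3 was chosen after its share was seen. Cxcl2, Dusp1 and Il1b had 3.68% ± 2.89, 2.98% ± 2.29 and 2.71% ± 2.34, and were highest in replicate 3, at 7.01%, 5.61% and 5.37%. The share was highest in replicate 3 for 13 of the 16 genes, in replicate 2 for Nfkbia and Tnip1 and in replicate 1 for Klf6, of which Tnip1 was chosen after its values were seen. A higher share in replicate 3 was not particular to early response genes. Of 5945 protein-coding genes, 4048 were higher and 1225 lower in replicate 3 than in replicate 2. Against replicate 1, 4026 were higher and 1356 lower in replicate 3.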

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

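Reads of phiX174, a bacteriophage genome that is commonly added to sequencing runs, were counted in each library although no comparison used them. The gene table gave phiX174 119230, 34452 and 31427 expected counts in replicates 1, 2 and 3, or 0.314%, 0.0927% and 0.0533% of all counts, far above the 3 counts taken as the limit. The ERCC spike-in sequences, an RNA mixture used as a standard, had a count of 0 in the gene table. In the second transcript table they had 2, 3 and 4 counts in replicates 1, 2 and 3, so that replicate 3 lay above that limit.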

How the results depend on the processing

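Each comparison was recomputed under the alternatives chosen before the data were examined. Of 71 recomputed values of the 10 comparisons, 62 kept their direction and side of the threshold, or, for counts, stayed within 1.5 times. The differences of the early lists from the late and the interferon-stimulated lists, and of the macrophage list from the other cell types, kept both under each alternative. The difference between nuclear and cytoplasmic lncRNAs turned to 0.11 with genes under 1 TPM left out, where 4 and 10 genes remained, and was -0.45 without length normalization. The count of genes that vary more than the trend was 116 with protein-coding genes alone and 59 to 129 with each replicate left out. The percentile of the spread of the early lists was 85.3 without replicate 3 and 100 without replicate 1 or 2. The percentile of the macrophage list was 37.1 on the log2(TPM + 1) scale. The retained-intron percentile was 98.3 in the second transcript table. Among pairs, 164 of 173 recomputed ratios kept direction and side. Leaving out genes under 1 TPM could not change the ratios of the 19 pairs that remained. Rescaling TPM changes a ratio within a library only through the added 1. Ratios kept under these settings therefore say little about stability. The Rela over Rel and Arg1 over Nos2 ratios turned to -1.29 and -0.16 without length normalization, and Ccl4 over Ccl3 to 0.23 without replicate 2, against -0.22 and -0.19 without replicate 1 and 3. The cause of these changes was not tested, except that fewer libraries or genes entered where some were left out. For the TPM of 107 named genes, alternatives were chosen after the data were seen. The second transcript table moved 82 of them by more than 1 SD, with 102 lower and 5 higher and a median ratio of 0.428 to the first (Tnf 451, Zfp36 375 and Lyz2 2433 TPM, but mt-Atp6 309 against 233, which was 120 without replicate 2), and rescaling to coding genes and lncRNAs, which multiplies each value by 2.74 to 4.19, moved all 107. No paired analysis was possible because there is 1 group. With 3 libraries, 29% of simulated 2-fold changes in 1 library were found by the spread test, so smaller differences between replicates were largely out of reach.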

Other observations

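The tests on Gm49369 were chosen after the result they bear on was seen, and each pattern weighed here was noticed in the same data on which it was tested. Differences in this part are in TMM-normalized log2 CPM. The bootstrap intervals were taken over genes, which are not independent replicates. They do not measure how a difference would vary between libraries. On the TPM scale the median of 11164 protein-coding genes differed by -0.40 in replicate 3 from the mean of the other libraries, and by -0.01 after TMM.

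Genes of antigen presentation differed between the libraries. The 5 class II antigen presentation genes were all higher in replicate 1, with a median log2 difference of 0.60 from the mean of the other libraries, above each of 10000 matched lists, and all lower in replicate 2, at -0.57. H2-Eb1 passed the edgeR test of spread over all genes, though 0 of the 5 passed with the DESeq2 dispersion trend, and Cd74, H2-Aa, H2-Ab1 and H2-Eb1 passed in edgeR when adjusted over the list alone. Over 5 scalings the median was between 0.60 and 0.76 in replicate 1 and between -0.57 and -0.19 in replicate 2. The values 0.76 and -0.19 were those of the TPM scale, where they were 0.65 and -0.45 relative to the median of all protein-coding genes. The 5 tested neutrophil genes were all higher in replicate 3, with a median of 0.63 at percentile 99.9, and all lower in replicate 2, at -0.55, although 0 of 5 passed the edgeR test of spread over all genes, 0 had an unadjusted p under 0.05 and 0 passed with the DESeq2 dispersion trend. The medians in replicates 3 and 2 were 0.21 and -0.32 in CPM without TMM and 0.04 and -0.10 on the TPM scale. Relative to the median of all protein-coding genes, that in replicate 3 was 0.64 after TMM, 0.29 in CPM and 0.45 in TPM. That in replicate 2 was -0.56, -0.39 and -0.36. The CPM and TPM scales add 1 before the log2, which understates differences of genes with low values, so leaving out TMM is not the only change. Proliferation genes had a median of -0.25 in replicate 1, with 8 of 10 lower, and glycolysis genes of -0.15, with 10 of 11 lower. Both lists stood apart from matched lists, at percentiles 0.07 and 0.47. On the TPM scale these medians were -0.11 and 0.02. Relative to the median of all protein-coding genes, which was 0.11 there, they were -0.22 and -0.10. The 4 tested dendritic cell genes were all higher in replicate 3, with a median of 0.52, but at percentile 96.3 they did not stand apart. That median was 0.22 in CPM without TMM and 0.01 on the TPM scale. Relative to the median of all protein-coding genes it was 0.30 and 0.41 on these scales.

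Nuclear RNAs were higher in replicate 3 than in replicate 2, with median differences from the other libraries of 1.52 and -1.82, or 0.60 and -0.47 on the TPM scale. Relative to the median of all protein-coding genes, the values on the TPM scale were 1.00 and -0.73. Of the 7 nuclear lncRNAs that could be tested, Malat1, Neat1, Xist, Kcnq1ot1 and Firre passed the edgeR test of spread, with log2 ratios of replicate 3 over replicate 2 of 2.93, 2.65, 2.23, 2.95 and 1.69, while Pvt1 and Airn had 0.13 and 0.49. A bias by GC content or transcript length of the kind seen among protein-coding genes was argued against. The median of the 7 was 2.23 before and 2.13 after the trend on both was removed (bootstrap 95% interval 0.55 to 2.85). That trend was fitted over protein-coding genes and held values beyond nearly all of theirs at a limit. It therefore cannot decide on a length bias of longer RNAs. A candidate explanation is that different amounts of nuclear RNA were carried into the cytosolic fraction, which would also raise transcripts with retained introns, and over 5945 protein-coding genes their share was higher in replicate 3 than in replicate 2 by a median of 0.679 percentage points (bootstrap 95% interval 0.617 to 0.728). The median shares were 1.03%, 0.428% and 1.97% in replicates 1, 2 and 3, and the second transcript table gave a median difference of 1.21, but their means were 5.34%, 5.71% and 6.62%, so the order of replicates 1 and 2 was not the same for the mean. Replicate 3 also had the most counts, and an effect of sequencing depth on the retained-intron shares was not tested. Small nuclear RNAs took 0.00921%, 0.00299% and 0.0211% of the counts in replicates 1, 2 and 3. 7SL RNA of the signal recognition particle had the same order, at 7.03%, 5.37% and 9.35%, so the order was not particular to nuclear RNA. The 11 tested cytoplasmic lncRNAs did not share it, with median differences of 0.05, -0.02 and -0.09. Nor did Rmrp and Rpph1, RNAs of RNA processing, which together took 0.599%, 0.927% and 1.18% of the counts. Replicate 1 was lowest there, although replicate 3 was again highest. No biological explanation was tested, because the labels give the replicates no difference.

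Early response genes had a median of -0.24 in replicate 3 and of 0.22 in replicate 2, although the immediate early genes among them did not stand apart in replicate 3, and nuclear lncRNAs and the neutrophil genes above were higher in replicate 3. The share of 7SL and other small RNAs was not tested, because these differences are measured after TMM, which removes a factor common to all genes. A bias by GC content or transcript length was argued against for replicate 3, with a median of -0.26 after its trend was removed (bootstrap 95% interval -0.32 to -0.15). Other explanations of this pattern, biological ones included, were not tested.

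Gm49369 had log2 CPM of 4.28, 4.29 and 9.90 in replicates 1, 2 and 3. Reads shared with the overlapping Ctsd are a candidate explanation. The second transcript table did not give the rise, and its log2(TPM + 1) was lower in replicate 3 than the mean of the others by a difference of -2.12. The CPM of Gm49369, Ctsd and Ifitm10 together, which was tested first and decided nothing, differed by 0.12 on the log2 scale, and the test on the second table replaced it after that value was seen. Ctsd and Ifitm10 did not lose the 895 CPM that Gm49369 gained (loss of -107 CPM, with 385 CPM between replicates 1 and 2), though the explanation predicts a loss. Ctsd alone had 12180.2, 11794.6 and 12094.5 CPM in replicates 1, 2 and 3. The fitted trend had a median coefficient of variation of 14.4% between libraries, so a loss of that size could go unseen. The missing loss therefore cannot decide, and the explanation stays open.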
